A study of Mus musculus with 6 samples.

How the data were processed

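RNA of 6 samples of sorted mouse bone marrow cells was hybridised to 6 one-colour Affymetrix mouse arrays, 3 of MLL-AF9/Mn1wt cells and 3 of MLL-AF9/Mn1null cells, with groups and replicate numbers as the sample titles give them. Per the labels' protocols, RNA was extracted with Trizol and 3 microgram of total RNA were converted to double-stranded DNA with a T7 promoter primer and transcribed with biotinylated nucleotides. The values deposited by the authors are log2 expression values per probe set, made with RMA per the submitters' processing notes. RMA subtracts background, quantile-normalizes arrays and summarises probes, so overall differences in RNA amount between samples are removed and low signals are compressed towards a floor. The RMA software version, any filter by the authors and the positions of the probes are not given in the sources used here. Scanner files were not used here.

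The table held 45101 probe sets, of which 64 are Affymetrix controls that were kept out of all tests. In the platform annotation, 34945 of the other 45037 probe sets named 1 gene, 932 named several and 9160 were not listed; only those with 1 gene were named. Entrez identifiers of 34741 probe sets were found in a RefSeq gene table (assembly GRCm38.p6), and 0 symbols changed. Each of 18193 genes was represented by its probe set with the highest mean over all 6 arrays, and 3513 genes whose mean lay under the 30th percentile of all probe sets (log2 4.07) were left out, which left 14680. Array medians lay between 5.17 and 5.23, and no normalization was added. A fold difference is 2 to the power of the difference of mean log2 values, and it understates the change where a group lies near the floor.

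Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without a block, as Mn1null minus Mn1wt, 2-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Unless another setting is named beside it, the adjusted p of a gene comes from this limma model. Each list of genes was tested with camera at its preset correlation of 0.01, with the p-values adjusted over the 32 lists of at least 5 tested genes, and again with the correlation estimated per list and with fry. The lists, written before the data were examined, covered the MLL-AF9 and HOX-MEIS program, stem and progenitor genes, primary and secondary granules, monocytes, dendritic cells, mast cells and basophils, eosinophils, erythroid cells, megakaryocytes, B cells, T and NK cells, stroma and endothelium, G1/S, G2/M, p53 targets, cyclin-dependent kinase inhibitors, apoptosis, interferon response, cytokines, retinoic acid, interleukin 3 and STAT5, ERK feedback, immediate early genes, the unfolded protein response, MYC and ribosome biogenesis, glycolysis and hypoxia, oxidative phosphorylation, cholesterol, lysosomes, integrins, cofactors named with MN1, and sex-linked genes as a check that was not tested as a list. They were drawn from general knowledge and not from these samples. The design, the alternatives and the rule for named genes were also fixed at that time. The rule takes Mn1, then the 12 largest rises and the 12 largest falls among genes past the threshold whose groups do not overlap, leaving out predicted genes, then up to 2 genes per direction of each list with the smallest p. Control probe sets were summarised per array and compared by group means and overlap.

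The same steps were tested on simulated data with the real genes' means and spread for the comparison of Mn1null with Mn1wt (14680 genes, 50 changed at each size). Differences of 0.25 were recovered for 22%, of 0.5 for 68%, of 1 for 94% and of 2 for 100% of the genes, 11 of 153 calls (7.19%) were false, and among 32 lists the 1 raised list and 0 others were called. The real comparison called 7170 genes, so the adjusted threshold was stricter in the simulation. The recovered shares therefore do not give the sensitivity of the real comparison. The simulated genes varied independently and the simulated lists were random. The list result therefore does not show how often camera calls unchanged lists of correlated genes. The alternatives tried were other rules for probe sets, other filters, quantile normalization, median centring, an intensity trend with robust eBayes, array weights, the replicate number as a block, a threshold of 0.01 and each array left out in turn. Probe sets designed for 1 transcript only were added as an alternative after seeing the data.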

Results

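Gene expression was measured in mouse bone marrow cells that carried MLL-AF9, a fusion oncogene of acute leukaemia, and that had either an intact Mn1 gene (Mn1wt, n = 3) or Mn1 deleted with CRISPR-Cas9 (Mn1null, n = 3). Mn1 encodes a transcriptional cofactor, and the comparison asks which transcripts differ when it is deleted in these cells. Per the labels, the cells had been sorted, had been transduced with a control vector for a green fluorescent protein in both groups, and had grown in medium with interleukin 3, interleukin 6 and stem cell factor. Each of the 6 arrays gave log2 values for 45101 probe sets, and the array medians lay between 5.17 and 5.23. Across the 14680 genes tested, arrays of the same group correlated at 0.997 to 0.998 and arrays of different groups at 0.968 to 0.969. The first principal component of the same genes took up 90.8% of the variance and separated the groups. The number of arrays limits the precision, and the median SD of a gene was 0.0748 in Mn1wt and 0.0718 in Mn1null. The labels do not say that replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

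Mn1 itself was read by 1 probe set, at 4.35 ± 0.20 in Mn1wt and 4.13 ± 0.071 in Mn1null (log2, SD, n = 3 each). The difference of -0.22 (95% interval -0.46 to 0.023) did not pass limma's test (adjusted p = 0.121), and both means lay just above the filter level of 4.07. Without Mn1wt replicate 2 the difference was -0.33 and passed (adjusted p = 0.00727). The position of this probe set relative to the deleted part of the gene is not given in the sources used here, so its signal neither checks nor contradicts the labels.

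Deletion of Mn1 went with very large shifts of a limited set of genes. Among the genes that rose, Frzb, which encodes a secreted Wnt-binding protein, went from 4.25 ± 0.048 to 11.20 ± 0.049 (SD, n = 3 each), a difference of at least 123-fold. Cdkn2a, the locus of the INK4A and ARF tumour suppressors, rose 29.5-fold from 6.41 ± 0.084 to 11.29 ± 0.042. Hdc, the enzyme that makes histamine, rose 23.7-fold, and Cyp11a1, the enzyme that starts steroid synthesis, rose 25.8-fold. Among the genes that fell, Hpgd, which inactivates prostaglandins, went from 12.41 ± 0.051 to 5.39 ± 0.13, a 130-fold difference, and the transcription factor gene Mef2c went from 11.18 ± 0.082 to 4.49 ± 0.027, a difference of at least 103-fold. The Mn1wt mean of Frzb and the Mn1null mean of Mef2c lay just above the filter level, so these folds are lower bounds.

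**Figure D1:**
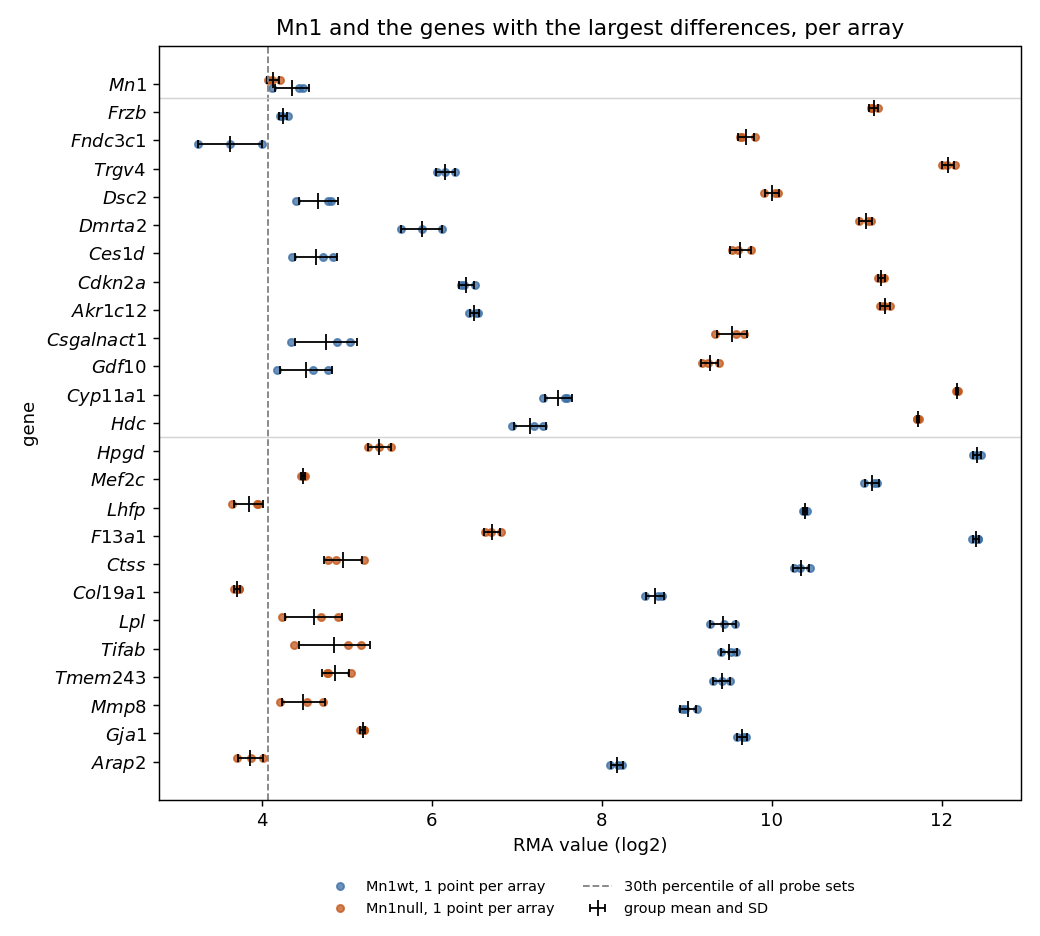
RMA values (log2) of Mn1 and of the 12 genes with the largest rises and the 12 with the largest falls, 1 point per array, with group means and SD (n = 3); the dashed line is the 30th percentile of all probe sets, 4.07. Mn1 lies near that line in both groups, while Frzb moves from 4.25 to 11.20 and Hpgd from 12.41 to 5.39.

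The other large rises on the log2 scale were those of Dsc2, a desmosomal cadherin, at 5.34 ± 0.115 (SE), the transcription factor gene Dmrta2 at 5.22 ± 0.120, the carboxylesterase Ces1d at 4.99 ± 0.129, the aldo-keto reductase Akr1c12 at 4.83 ± 0.054, Csgalnact1, which acts in chondroitin sulfate synthesis, at 4.78 ± 0.183, and the TGF-beta family member Gdf10 at 4.75 ± 0.15. Trgv4, a variable segment of the T cell receptor gamma locus, rose by 5.91 ± 0.071, and Fndc3c1 by 6.07 ± 0.175. Trgv4, Akr1c12 and Ces1d belong to families of related genes, and the specificity of their probe sets was not checked. The other large falls were those of F13a1, the A subunit of coagulation factor XIII, at -5.69 ± 0.060, the lysosomal protease Ctss at -5.39 ± 0.113, lipoprotein lipase Lpl at -4.82 ± 0.168, Tifab at -4.64 ± 0.194, Tmem243 at -4.54 ± 0.093, neutrophil collagenase Mmp8 at -4.53 ± 0.126 and the gap junction gene Gja1 at -4.46 ± 0.049. Lhfp (-6.54), Col19a1 (-4.91) and Arap2 (-4.31) also fell, and their Mn1null means lay under the filter level, as the Mn1wt mean of Fndc3c1 did, so these differences are compressed. Low means just above that level, such as those of Frzb, Mef2c, Mmp8 and Gdf10, can compress a difference as well. For these 24 genes limma's adjusted p lay between 6.71e-09 (Frzb) and 3.52e-06 (Tifab).

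Of the 14680 genes tested, 7170 (48.8%) passed limma's test at an adjusted p of 0.05, with 3413 higher and 3757 lower in Mn1null. Of these, 892 differed at least 2-fold, 554 of them higher and 338 lower, and 4975 differed by less than 1.5-fold. A difference of at least 8-fold was reached by 52 genes that rose and 39 that fell. The 3 Mn1null values lay all above or all below the 3 Mn1wt values for 8465 genes (57.7%), against a chance share of 10%.

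The labelling controls also differed between the groups. These are bacterial transcripts (dap, lys, phe, thr) of the kind added to RNA before labelling. Their 5′ probe sets averaged 7.32 ± 0.10 in Mn1wt and 6.47 ± 0.059 in Mn1null, a difference of -0.85, and 8 of 8 probe sets did not overlap between the groups. The middle probe sets differed by -0.49 and the 3′ probe sets by -0.30, while the hybridisation controls (bioB, bioC, bioD, cre) differed by -0.09. Among mouse control transcripts, the 3′ minus 5′ difference was higher in Mn1null without overlap for pyruvate carboxylase (by 0.49) and 18S RNA (0.27), and changed with overlap by 0.089 for the transferrin receptor, 0.034 for Gapdh and -0.011 for beta-actin. Every gene group described here was compared between these same arrays.

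**Figure D2:**
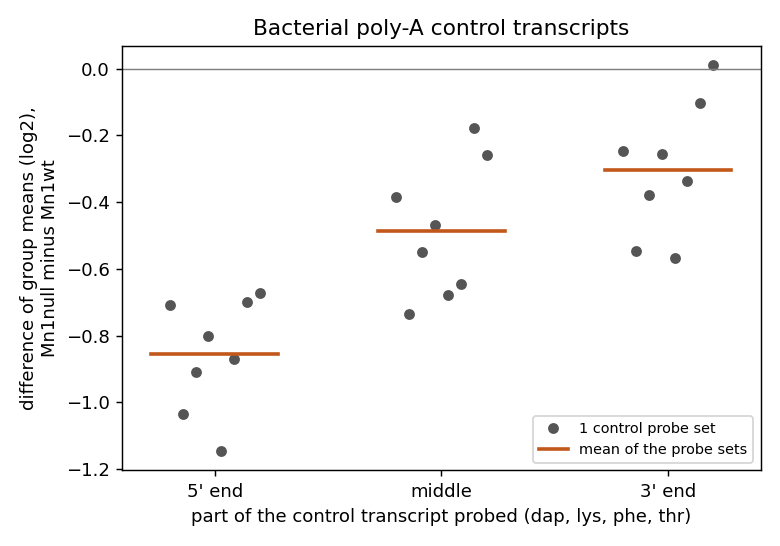
Difference of the group means (log2, Mn1null minus Mn1wt) for each probe set of the bacterial control transcripts dap, lys, phe and thr, by the part of the transcript probed; the line is the mean of the 8 probe sets of each part. The means are -0.85 at the 5′ end, -0.49 in the middle and -0.30 at the 3′ end.

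Of 32 gene lists, camera with its preset correlation called 14, of which 10 were higher and 4 lower in Mn1null. With an estimated correlation camera called 0, and 9 lists had an unadjusted p under 0.05, against 16 with the preset correlation. Fry, which asks only whether the genes of a list move on balance one way, called 27; its adjusted p is given where camera did not call a list and fry did. Counts adjusted over the list alone equalled those over all genes tested except where both are given.

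Mast cell and basophil genes rose together in Mn1null. Of 24 tested, 18 rose, 1 fell and 5 did not pass, with a median of 1.87 and a camera adjusted p of 1.65e-10 (adjusted p = 0.0555 with an estimated correlation). Cpa3, a mast cell carboxypeptidase, rose 17.5-fold from 8.19 ± 0.047 to 12.32 ± 0.011 (SD, n = 3 each), and the granzyme Gzmb rose 7.16-fold. Kit, the stem cell factor receptor, was high in both groups (10.44 and 10.28) and fell by 0.17, a call that was lost with the mean of its probe sets (adjusted p = 0.0985), with quantile normalization (0.0821), on another probe set (-0.090, adjusted p = 0.442) and when any 1 of 3 arrays was left out. Of the 24 genes, 19 had an Mn1wt mean above the median of all probe sets, and 6 belong to another list as well. Eosinophil genes rose too, 5 of 6 tested, while 0 passed limma's test downward (0 at an unadjusted p under 0.05), with a median of 2.64 (camera adjusted p = 0.00145; adjusted p = 0.134 with an estimated correlation). The eosinophil granule genes Prg2 and Epx rose by 3.51 ± 0.086 (SE) and 2.63 ± 0.071. In the same arrays the 5′ labelling controls differed by -0.85.

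Monocyte and macrophage genes fell as a group. Of 40 tested, 22 fell, 10 rose (11 adjusted over the list alone) and 8 did not pass over all genes, with a median of -0.42 (camera adjusted p = 0.00969; adjusted p = 0.183 with an estimated correlation). F13a1 and Ctss, given above, fell most clearly, while the Fc gamma receptor genes Fcgr3 and Fcgr4 rose by 1.87 ± 0.075 (SE) and 2.05 ± 0.091. With a filter at the 50th percentile of signal the list was no longer called (adjusted p = 0.103). Of the 40 genes, 34 had an Mn1wt mean above the median of all probe sets, and 6 belong to another list. The 5′ labelling controls were lower by the same -0.85 in these arrays.

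Neutrophil genes moved in both directions. Of 25 secondary granule and mature neutrophil genes, 14 rose and 6 fell, with a median of 0.43 (camera adjusted p = 0.0241; adjusted p = 0.183 with an estimated correlation). S100a9, a calcium-binding protein of mature neutrophils, rose by 2.21 ± 0.050 (SE), while Mmp8 fell by 4.53 and Trem3 by 0.64. Cyp4f18 rose by 2.86 on the probe set used, and its other probe set gave -0.22 (adjusted p = 0.190). Of 18 primary granule genes, 9 rose and 6 fell, and camera did not call the list (median 0.134, adjusted p = 0.295; fry upward, adjusted p = 3.84e-05). Cst7 (3.57 ± 0.064) and Nkg7 (1.62 ± 0.063) rose, while haptoglobin Hp (-1.07 ± 0.058) and proteinase 3 gene Prtn3 (-0.46 ± 0.041) fell. Prtn3 was among the highest signals in both groups, at 14.31 and 13.85.

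Genes of the MLL-AF9 and HOX-MEIS program moved in both directions. Of 26 tested, 6 rose and 10 fell, with a median of -0.12, and camera did not call the list (adjusted p = 0.393), while fry called it downward (adjusted p = 1.16e-04). Mef2c, a known member of this program, had the strongest fall of the list, and Hoxa5 fell by 1.81 ± 0.048 (SE). Pbx3, a HOX cofactor gene, rose by 2.37 ± 0.082, and Igf1r by 0.89 ± 0.056 (another probe set 0.12, adjusted p = 0.214). Hoxa9 went from 12.26 ± 0.031 to 11.95 ± 0.029 (SD, n = 3 each), a difference of -0.31 (limma adjusted p = 0.0011), and Meis1 differed by 0.24 (adjusted p = 0.00367), a call lost with the mean of its probe sets (0.12, adjusted p = 0.120), of which others gave 0.15 and -0.0235, and with probe sets designed for 1 transcript only (0.15, adjusted p = 0.377). The last 2 genes also stand in the list of cofactors and partners named with MN1, of whose 18 tested genes 5 rose and 5 fell (median 0.0852, camera adjusted p = 0.593). There Stat3 rose by 0.62 ± 0.043, with 0.18 and 0.12 on other probe sets that did not pass, and Smarcd2, a chromatin remodelling subunit, fell by 0.31.

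Stem and early progenitor genes were more often higher. Of 26 tested, 13 rose and 6 fell, with a median of 0.167 (camera adjusted p = 0.0225; adjusted p = 0.193 with an estimated correlation). Myct1 (1.97 ± 0.054, SE) and the adhesion receptor gene Adgrg1 (1.78 ± 0.049) rose, whereas Prdm16, a regulator of stem cell maintenance, fell by 2.05 and the cell cycle inhibitor gene Cdkn1c by 1.53.

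Megakaryocyte and platelet genes rose, 12 of 23 tested, while 4 fell (5 adjusted over the list alone); the median was 0.41 (camera adjusted p = 0.0106; adjusted p = 0.134 with an estimated correlation). Itga2b, the platelet integrin alpha chain CD41, rose 12.3-fold from 7.92 ± 0.12 to 11.54 ± 0.11 (SD, n = 3 each), and thrombospondin gene Thbs1 rose 6.70-fold. Selp, which encodes P-selectin, fell by 2.69 ± 0.055 (SE) on the log2 scale, and platelet factor Pf4 by 0.98 ± 0.061. Of 21 erythroid genes, 9 rose and 4 fell, and camera did not call the list (median 0.170, adjusted p = 0.0682). It was called upward by fry (adjusted p = 1.90e-04), and by camera without a filter (adjusted p = 0.0388), with a filter at the 50th percentile (median 0.45, adjusted p = 0.0438), with probe sets designed for 1 transcript only (median 0.30, adjusted p = 0.0269) and without Mn1null replicate 1 (adjusted p = 0.0372). Gata1, a transcription factor of the erythroid, megakaryocyte and mast cell lineages, rose by 1.76 ± 0.075, and Icam4 by 2.11 ± 0.057. The globin genes Hbb-bh1 (-2.06 ± 0.125) and Hba-a2 (-0.79 ± 0.079) fell.

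**Figure D3:**
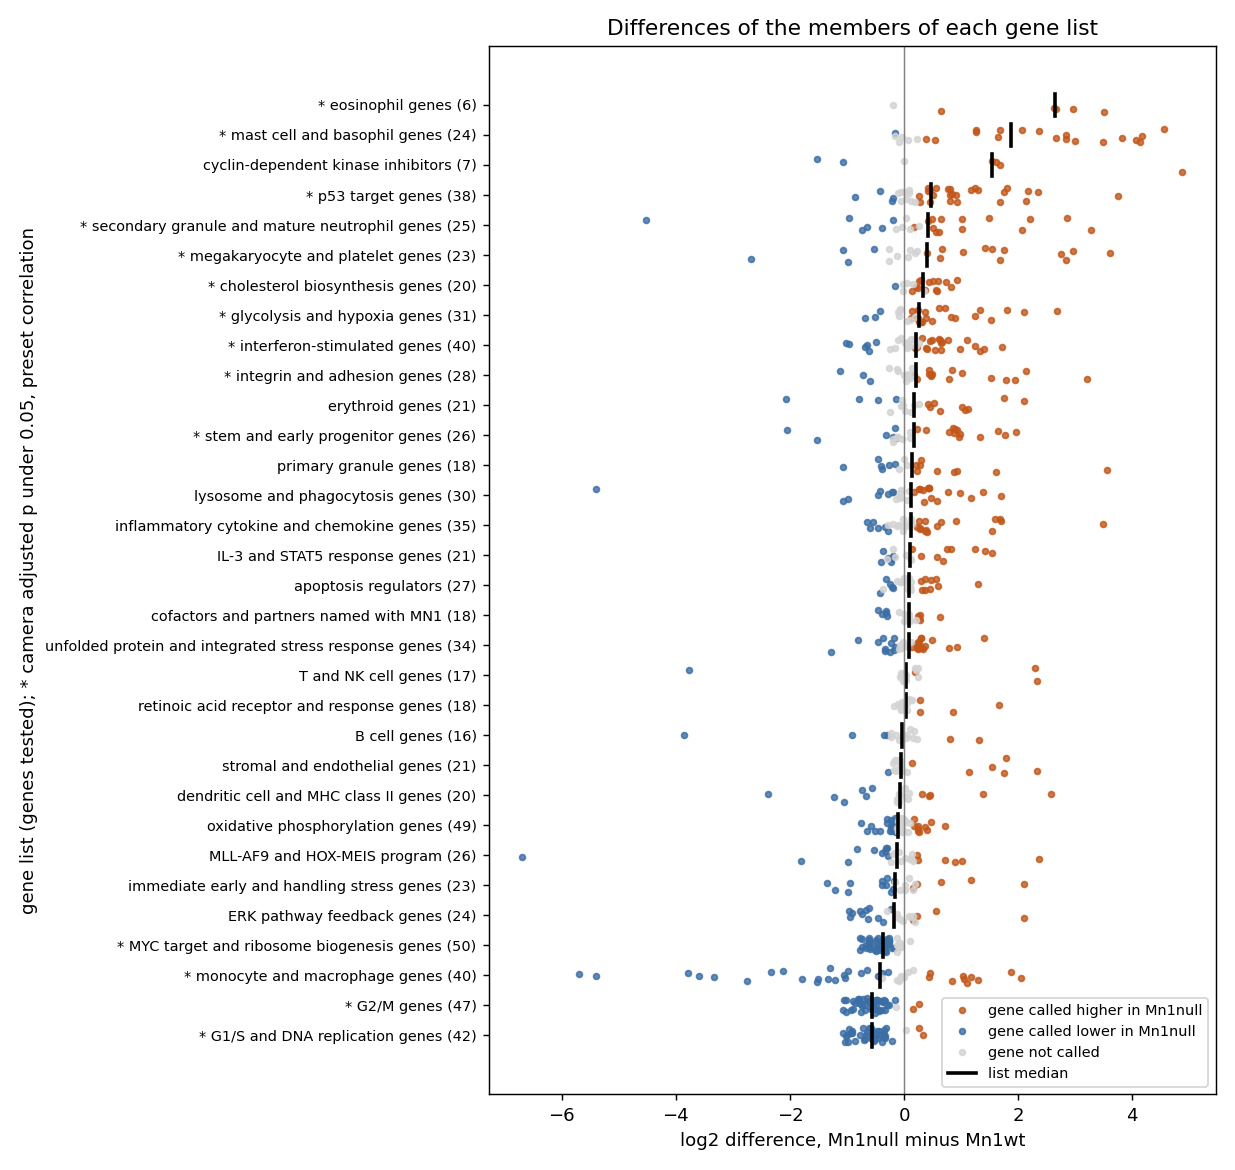
Log2 difference (Mn1null minus Mn1wt) of every tested member of the 32 lists, 1 point per gene, coloured by limma's call, with the list median as a black bar; the number tested stands in brackets and an asterisk marks a camera adjusted p under 0.05 with the preset correlation. Mast cell and basophil genes have a median of 1.87, and G1/S genes one of -0.56.

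Genes of DNA replication, mitosis and ribosome biogenesis fell nearly throughout, each by a moderate amount. Of 42 G1/S and DNA replication genes, 39 fell and 2 rose (median -0.56, camera adjusted p = 5.38e-13; adjusted p = 0.0555 with an estimated correlation). Ccne1, which encodes cyclin E1, went from 10.03 ± 0.024 to 9.04 ± 0.032 (SD, n = 3 each), and the ribonucleotide reductase gene Rrm2 from 12.63 ± 0.023 to 11.60 ± 0.048. The exceptions were E2f8 (0.26 ± 0.043, SE) and E2f2 (0.33 ± 0.107), both transcription factors of the cell cycle. The call of E2f2 was lost with the replicate block (adjusted p = 0.0665), with quantile normalization (0.0809), with array weights (0.0710), on its other probe set (0.14, adjusted p = 0.249) and when any 1 of 4 arrays was left out. Of 47 G2/M genes, 44 fell and 2 rose (median -0.55, camera adjusted p = 8.03e-14; adjusted p = 0.127 with an estimated correlation). The mitotic kinesin Kif23 fell by 1.04 and the kinase Aurka by 1.02. The 2 that rose were Gtse1 (0.26) and Pttg1 (0.16), and both calls were lost when single arrays were left out. That of Pttg1 was also lost with the replicate block (adjusted p = 0.0578), with median centring (0.0734) and with the mean of its probe sets (0.010, adjusted p = 0.890), of which the others gave -0.22 and 0.092. Of 50 MYC target and ribosome biogenesis genes, 41 fell (44 adjusted over the list alone) and 0 rose (also 0 at limma's unadjusted p under 0.05; median -0.36, camera adjusted p = 9.81e-12; adjusted p = 0.134 with an estimated correlation). The nucleolar genes Nolc1 and Utp20 fell by 0.74 ± 0.044 and 0.77 ± 0.050. The 5′ labelling controls differed by -0.85 in the same arrays.

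p53 target genes rose in Mn1null. Of 38 tested, 25 rose (26 adjusted over the list alone) and 4 fell, with a median of 0.48 (camera adjusted p = 6.48e-07; adjusted p = 0.0863 with an estimated correlation). Perp, an apoptosis effector, rose 13.5-fold from 7.12 ± 0.12 to 10.87 ± 0.083 (SD, n = 3 each), and Zmat3, a zinc finger gene induced by p53, rose 5.07-fold. Tigar (-0.85 ± 0.119, SE) and Ckap2 (-0.41 ± 0.048) fell. Of the 38 genes, 12 belong to another list as well. Among 7 cyclin-dependent kinase inhibitors, 4 rose and 2 fell, and camera did not call the list (median 1.53, adjusted p = 0.121; fry upward, adjusted p = 2.54e-06). Besides Cdkn2a, Cdkn2c rose by 1.53 ± 0.044, while Cdkn1b fell by 1.06 ± 0.049 and Cdkn1c by 1.53 ± 0.206. Of 27 apoptosis regulators, 9 rose and 5 fell (median 0.0858, camera adjusted p = 0.198, fry upward with 1.90e-04). The p53-induced BH3-only gene Bbc3 rose by 1.31 ± 0.064 and Diablo by 0.60 ± 0.043 (another probe set 0.29, adjusted p = 0.235), while cytochrome c gene Cycs fell by 0.43, with 0.18 on another of its probe sets, and Bak1 fell by 0.25.

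Glycolysis and hypoxia genes and cholesterol biosynthesis genes rose. Of 31 glycolysis and hypoxia genes, 21 rose and 3 fell (median 0.26, camera adjusted p = 8.84e-05; adjusted p = 0.173 with an estimated correlation). Ankrd37, a hypoxia-inducible gene, rose 6.43-fold and the aldolase Aldoc 4.29-fold, while the oxygen-sensing hydroxylase genes Egln3 (-0.68 ± 0.045, SE) and Egln1 (-0.42 ± 0.059) fell. Of 20 cholesterol biosynthesis genes, 14 rose (16 adjusted over the list alone) and 1 fell (median 0.33, camera adjusted p = 2.67e-04; adjusted p = 0.233 with an estimated correlation). Nsdhl rose by 0.92 ± 0.057 and Msmo1 by 0.74 ± 0.053, and Ebp, the gene that fell, differed by -0.16 and lost its call with quantile normalization (adjusted p = 0.0607) and when any 1 of 4 arrays was left out. Of 49 oxidative phosphorylation genes, 10 rose and 21 fell (median -0.11, camera adjusted p = 0.165, fry downward with 0.0232). Cyc1 of complex III fell by 0.76 ± 0.052 and Ndufs1 of complex I by 0.57 ± 0.051, while Ndufa1 rose by 0.72 ± 0.047 and Ndufa6 by 0.48 ± 0.047. Of 30 lysosome and phagocytosis genes, 15 rose and 8 fell (median 0.130, camera adjusted p = 0.163, fry upward with 5.50e-04). The lysosomal glycosidases Glb1 and Man2b1 rose by 1.70 ± 0.052 and 1.39 ± 0.051, and the protease gene Ctsl fell by 0.98 ± 0.048.

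Adhesion genes and interferon-stimulated genes rose as lists. Of 28 integrin and adhesion genes, 15 rose and 3 fell (median 0.21, camera adjusted p = 0.0011; adjusted p = 0.134 with an estimated correlation). Itgal, the alpha chain of the leukocyte integrin LFA-1, rose 9.24-fold from 8.62 ± 0.047 to 11.83 ± 0.024 (SD, n = 3 each), and Itgb7 rose 3.84-fold, while Itgb5 fell by 1.12 ± 0.085 (SE) and Alcam by 0.72 ± 0.094. Of 40 interferon-stimulated genes, 20 rose and 6 fell (median 0.21, camera adjusted p = 0.00969; adjusted p = 0.183 with an estimated correlation). Sp100, a nuclear body component, rose by 1.72 ± 0.084 and the nuclease gene Isg20 by 1.33 ± 0.046, whereas the antiviral genes Oas1a (-1.02 ± 0.070) and Gbp3 (-0.96 ± 0.048) fell. With probe sets designed for 1 transcript only, the interferon, stem cell and secondary granule lists were not called (adjusted p = 0.0537, 0.0694 and 0.0537).

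Camera called no signalling list in the planned fit, though some were called under other settings. Of 35 inflammatory cytokine and chemokine genes, 16 rose and 6 fell (median 0.124, camera adjusted p = 0.0539). The list was called upward by fry (adjusted p = 2.00e-05), and by camera without a filter (adjusted p = 0.0379), with median centring (0.0442), with array weights (0.0459), with probe sets designed for 1 transcript only (0.0477) and when any 1 of 3 arrays was left out. Il6 rose 11.2-fold from 6.76 ± 0.068 to 10.24 ± 0.047 (SD, n = 3 each) and the chemokine Ccl6 3.01-fold, while Tnf fell by 0.60 and Cxcl10 by 0.65. Of 21 interleukin 3 and STAT5 response genes, 9 rose and 6 fell (7 adjusted over the list alone; median 0.110, camera adjusted p = 0.259, fry upward with 5.06e-04), with Osm at 1.54 ± 0.062 (SE), Ccnd3 at 0.83 ± 0.046, Cd69 at -0.41 ± 0.046 and Pim3 at -0.22 ± 0.045. Another probe set of Ccnd3 gave 0.013 and others of Pim3 -0.055 and -0.16, which did not pass. Of 24 ERK pathway feedback genes, 4 rose and 11 fell (12 adjusted over the list alone; median -0.18, camera adjusted p = 0.146, fry downward with 0.0171), and camera called the list with probe sets designed for 1 transcript only (median -0.26, adjusted p = 0.0443). The phosphatase gene Dusp6 fell by 0.91 ± 0.051 and Etv5 by 0.78 ± 0.042 on the probe set used, with -0.066 (adjusted p = 0.775) and -0.12 (adjusted p = 0.484) on its others, whereas the immediate early gene Egr1 rose by 2.10 ± 0.045 and the ephrin receptor gene Epha2 by 0.57 ± 0.085. Of 23 immediate early and handling stress genes, 5 rose (6 adjusted over the list alone) and 11 fell (median -0.16, camera adjusted p = 0.344), with Dusp1 at 0.65 ± 0.071, Zfp36 at -0.97 ± 0.049 and Hsp90aa1 at -0.38 ± 0.041 (another probe set -0.068, adjusted p = 0.518). Of 34 unfolded protein and integrated stress response genes, 16 rose and 11 fell (median 0.0796, camera adjusted p = 0.385, fry upward with 0.00657), with Dnajb9 at 1.40 ± 0.066, Ppp1r15a at 0.79 ± 0.065, Creld2 at -0.80 ± 0.062 and Phgdh at -0.46 ± 0.047. Of 18 retinoic acid receptor and response genes, 4 rose and 0 fell (also 0 at limma's unadjusted p under 0.05; median 0.0281, camera adjusted p = 0.292, fry upward with 0.00476), led by transglutaminase Tgm2 (1.66 ± 0.070) and the corepressor gene Nrip1 (0.87 ± 0.062; another probe set 0.14, adjusted p = 0.197).

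Camera called no list of markers of other blood and stromal cells. Of 20 dendritic cell and MHC class II genes, 5 rose and 6 fell (median -0.0764, camera adjusted p = 0.754); Clec10a (2.58 ± 0.083, SE) and H2-DMa (1.38 ± 0.046) rose, and Cd74, the invariant chain, (-1.22 ± 0.085) and Tcf4 (-1.05 ± 0.058; another probe set -0.27, adjusted p = 0.0911) fell. The MHC class II genes H2-Aa (-2.39 ± 0.20), H2-Ab1 (-0.73 ± 0.087) and H2-Eb1 (-0.66 ± 0.061) fell as well. Camera gave this list a downward and fry an upward direction. Of 16 B cell genes, 2 rose and 4 fell (median -0.0280, camera adjusted p = 0.803). Cd72 (1.31 ± 0.076) and Vpreb1 (0.81 ± 0.090) rose, and Cd79b fell by 0.91. The heavy chain gene Ighm fell by 3.86 on the probe set used and by 3.89 on another, while further probe sets gave 0.17, 0.073, 0.025, -0.0043, -0.080 and -0.11 and did not pass. Of 17 T and NK cell genes, 3 rose and 1 fell (median 0.0324, camera adjusted p = 0.337). Thy1, a surface glycoprotein of T cells and stromal cells, rose 5.06-fold from 9.84 ± 0.051 to 12.18 ± 0.065 (SD, n = 3 each) and the adaptor Lat rose 4.92-fold, while Cd28 fell by 3.78 to a level under the filter. Of 21 stromal and endothelial genes, 6 rose and 1 fell; the median was -0.0600, the mean 0.339 and camera's direction upward, and camera did not call the list (adjusted p = 0.412), while fry called it upward (adjusted p = 2.14e-04). Pecam1, an adhesion molecule of endothelium and leukocytes, rose by 1.78 ± 0.064, and Dcn, the gene that fell, differed by -0.27, a call lost with the intensity trend and robust eBayes (adjusted p = 0.0504). Of the sex-linked check genes, Xist read 12.14 ± 0.084 in Mn1wt and 12.44 ± 0.022 in Mn1null (SD, n = 3 each); its difference of 0.31 turned to -1.32 on another probe set and to -0.23 with the mean of its probe sets. Probe sets of the Y-linked genes Eif2s3y, Kdm5d and Uty lay between 2.61 and 3.96 in both groups, under the filter level.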

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

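The tests on mature mast cells, on a lower monocyte share and on basophils or eosinophils were chosen only after the results were seen.

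Outside the named genes, 5131 probe sets that name no single gene lay above the filter, and 1284 of them (25.02%) passed limma's threshold when all probe sets were tested by themselves, 600 higher and 684 lower in Mn1null, with 156 differing at least 2-fold. That share was below the 41.56% of all 31526 probe sets in the same fit, so they are listed only because the gene comparison leaves them aside, and the transcripts behind them are unnamed here. The 5′ probe sets of the labelling controls dap, lys, phe and thr are listed for the same reason, with a difference of -0.85 and 8 of 8 probe sets not overlapping.

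The labelling controls fell more at their 5′ than at their 3′ ends. The 3′ minus 5′ difference of the mouse controls was higher in Mn1null for pyruvate carboxylase (by 0.49) and 18S RNA (0.27). For the transferrin receptor (0.089), Gapdh (0.034) and beta-actin (-0.011) the groups overlapped. More 3′-biased labelling in the Mn1null arrays could account for part of the gene differences, though not all mouse controls showed it. For genes that differed at least 2-fold, 94.42% of 430 other probe sets of the same genes had the same sign, with a median ratio of 0.707. Among those that rose the share was 95.94% of 246, and among those that fell it was 92.39% of 184. The direction therefore held on another probe set for most of them. Neither share can decide on such labelling, since where each probe set lies in its transcript is not given in the sources used here. For the falls, the labelling controls also averaged lower at every part probed. For genes that differed by less than 2-fold the share was 84.21% of 3490, between the bounds set for a decision. Labelling and genotype thus cannot be told apart for these small differences either. The labels do not say whether each group was labelled in a run of its own, and the genotype stays open as a biological explanation. Nor do they say whether the replicates are separate cultures, clones or animals. Other differences between the 2 cell populations therefore cannot be told apart from genotype.

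Mast cell, basophil and eosinophil genes were higher and monocyte genes lower in Mn1null, which may reflect a change within the MLL-AF9 cells or a different mixture of cells. The mast cell and basophil median lay 1.737 above that of the primary granule genes (permutation p = 0.0077 over genes, which are not independent replicates). This cannot decide on a lower share of monocytic cells alone. The mast cell list was compared after its rise was seen, and whether monocytic cells carried the primary granule genes was not measured. Mature mast cells mixed into the Mn1null samples stay open, since their protease genes Cma1, Tpsb2 and Tpsab1 (median difference -0.0842) lay near the filter level in both groups, where they exclude nothing. Basophils or eosinophils mixed into the samples stay open too. Of their granule genes Mcpt8 (0.55), Prg2 (3.51) and Epx (2.63), 3 of 3 were higher, but they belong to the lists that form the pattern, so the count decides nothing. A difference between genotypes stays open as well. The labels say that the cells were sorted but not by which marker.

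Replication, G2/M and ribosome biogenesis genes were lower in Mn1null. A trend of the differences with signal intensity is argued against, since the medians of all 3 lists lay at percentile 0 of 10000 random lists matched on mean signal. Of 98 other probe sets of these genes, 92.86% were lower as well. This cannot decide on more 3′-biased labelling, since the labelling controls averaged lower at their 5′ (-0.85), middle (-0.49) and 3′ (-0.30) probe sets. The genotype, the difference that the design names, stays open and was not tested apart from the arrays' labelling.

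The 6 arrays make only 10 splits into groups of 3, too few for a share under 0.05. The real split gave 7170 genes, 892 genes changed at least 2-fold and 14 lists, and the highest of the other splits gave 0, 0 and 9; in each case 1 of the 10 splits, the real one, reached the real value. Every other split mixes the genotypes within its groups, which widens the spread there, so its gene counts of 0 decide nothing. These splits still called 4 to 9 lists.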

How the results depend on the processing

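The alternative with probe sets designed for 1 transcript only was chosen after seeing the data. The count of genes past the threshold was 5460 to 7590 under the alternatives fixed in advance that count genes, 6049 with probe sets designed for 1 transcript only, and 6386 to 6683 with single arrays left out. With every probe set tested by itself it was 12163 probe sets, and 1447 of them (873 higher, 574 lower) differed at least 2-fold, since 26395 probe sets that name 1 gene entered. The count of genes changed at least 2-fold was otherwise 699 to 900, and 883 to 898 with single arrays left out. Camera called 14 to 16 lists under the other settings, 0 with an estimated correlation and 27 with fry. The cause was not tested, but fry does not compare a list with other genes. Some lists lost camera's call though their estimated correlation lay below the preset 0.01, such as the eosinophil (-0.124) and megakaryocyte (-0.0327) lists. Other lost lists lay above it, such as the mast cell and basophil list (0.0194). A higher correlation therefore does not account for every loss, and the adjusted p with an estimated correlation does not reflect correlation alone. The difference of Mn1 ranged from -0.33 to -0.15 with single arrays left out and passed only without Mn1wt replicate 2 (-0.33, adjusted p = 0.00727); its adjusted p was otherwise 0.0949 to 0.307.

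Replicate numbers 1, 2 and 3 stand in both groups, but deviations of same-numbered arrays correlated at -0.0394, 0.109 and 0.0804, and 1 of 3 Mn1wt arrays correlated best with its own number, so the arrays share only a number. With the replicate block 6943 genes passed, 6669 of them shared with the unblocked fit, 892 differed at least 2-fold, 14 lists were called and Mn1 differed by -0.22.

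Of 134 named genes, 20 lost the call or turned under at least 1 setting. Those that turned did so on another probe set: Cyp4f18 (-0.22), Ighm (0.17, 0.025 and 0.073), Pttg1 (-0.22), Cycs (0.18), Meis1 (-0.0235) and Xist (-1.32). Xist also turned with the mean of its probe sets (-0.23), and with probe sets designed for 1 transcript only Pttg1 turned (-0.22); the cause was not tested. Another probe set missed the threshold for Igf1r, Tcf4, Kit, Ighm, E2f2, Pttg1, Diablo, Nrip1, Ccnd3, Pim3, Etv5, Hsp90aa1, Stat3 and Meis1. A named gene kept its direction and lost its call in 33 other comparisons with an alternative and in 20 with a single array left out, against 1388 and 784 that did neither. For lists, 18 comparisons lost and 21 gained a call, and 4 gained one with a single array left out. Scaling moved the median of all genes little, to -0.00731 with quantile normalization and -0.015 with median centring. Signal over background limits genes near 4.07, where differences are compressed: 62 of the 892 genes had a group mean under it.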

Other observations

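The gene families in the next 2 paragraphs were chosen after their values were seen, and their directions were the same under both scaling alternatives. Within the Hoxb cluster, a group of neighbouring homeobox genes, 4 of 5 genes tested fell in Mn1null by limma's test, with Hoxb2 at -3.33 ± 0.175 (SE), Hoxb5 at -1.79 ± 0.142, Hoxb4 at -1.54 ± 0.125 and Hoxb9 at 0.010 (limma adjusted p = 0.932). Of 8 Hoxa genes tested 4 fell as well and 1 rose, with Hoxa5 at -1.81 and Hoxa11 at 1.04. Of 7 Hoxc and Hoxd genes 0 passed limma's test in either direction (also 0 at an unadjusted p under 0.05). The median was -1.54 for Hoxb, -0.27 for Hoxa and 0.046 for Hoxc and Hoxd genes. The clusters were not tested against each other. Proteasome subunit genes were lower, 28 of 34 with 2 higher and a median of -0.33. Psmd11 (-0.55 ± 0.061) and Psma6 (-0.49 ± 0.042) are examples.

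Genes of histamine and leukotriene metabolism also moved, in part as members of the mast cell and basophil list given in the report, to which Hdc, Slc18a2, Alox5, Cd200r3 and Cd200r4 belong. Hdc, which makes histamine, and Slc18a2, which stores it in granules, rose by 4.56 and 3.83 on the log2 scale, while Hnmt, which breaks it down, fell by 3.95. All 4 tested genes of leukotriene synthesis rose, Alox5 by 2.66 ± 0.042 (SE), Ltc4s by 1.44 ± 0.064, Alox5ap by 0.53 ± 0.042 and Lta4h by 0.23 ± 0.047. The CD200 receptor genes Cd200r1, Cd200r3 and Cd200r4 rose by 2.46, 4.06 and 4.17; related sequences within this family were not separated. Of 18 glutathione transferase and aldo-keto reductase genes, 10 rose, among them Gstm4 (1.01 ± 0.051), and the others did not pass. Of 4 embryonic globin and alpha-fetoprotein genes, 3 fell, among them Hbb-y (-1.70 ± 0.063) and Afp (-2.63 ± 0.052), and Hba-x differed by 0.013 (limma adjusted p = 0.863).

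A gain or loss of a whole chromosome in either group was tested as a hypothesis through the median difference of each autosome over 7114 genes above the median signal. The autosome farthest from 0 was chromosome 16 at -0.1256, which argues against it as far as expression medians show.

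The rise of Cdkn2a, read by 1 probe set, might come from a loss of the Cdkn2a neighbourhood in the Mn1wt samples. Mtap, the next gene, differed by -0.2555 (limma adjusted p = 0.0134), that is, it was higher in Mn1wt, which argues against a loss that includes Mtap. Cdkn2b, the neighbour on the other side, was 1.62 higher in Mn1null (limma adjusted p = 5.38e-05), which a loss in Mn1wt would give as well. A loss that spares Mtap stays open, as does a difference in the regulation of the locus. A difference of Trp53 itself had been planned as a further explanation for the rise of Cdkn2a and p53 targets, and it was not examined here.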
